A study of Danio rerio with 7 samples.

How the data were processed

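Gene expression was measured in sox10-positive cells sorted from dissociated zebrafish (Danio rerio) embryos. The labels list 7 samples: uninjected embryos in DMSO, uninjected embryos in progesterone, and embryos injected with a ctr9 morpholino in DMSO or in progesterone. Ctr9 is a subunit of the PAF1 complex, which travels with RNA polymerase II during transcription elongation, and a morpholino is an antisense oligonucleotide that blocks translation or splicing of its target. Per the labels' protocols, embryos were raised at 28 °C and exposed to 32 µM progesterone or to DMSO between 50% epiboly and the stage of 15 somites, ribosomal RNA was removed before a low-input library preparation, and paired reads of 100 bases were sequenced.

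The authors deposited 1 table of FPKM (fragments per kilobase of transcript scaled to library size) with gene identifiers, gene names and 6 library columns. The unit was taken from a stray header line at the foot of the table, which was removed (1 row), leaving 33827 entries, 33735 of them genes. Per the submitters' processing notes, the tools were cutadapt, TopHat2 2.0.11 and Cufflinks 2.2.1, and the genome builds named are Zv9 and hg19, with no role given for either. The annotation version is not given in the sources used here. Of the gene identifiers, 21937 were found in a name table that was used only to match list symbols to current names. No coordinates were used. The table also holds 92 ERCC spike-in transcripts, whose amounts are not in the labels. They were not set apart in advance, so 10 of them are among the 13155 genes tested, and none was called.

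The 6 columns were assigned by their names. Those of the morpholino libraries carry the experiment numbers of the labels, 2 in DMSO and 2 in progesterone. Those of the uninjected DMSO libraries are named by an amount, 5 ng and 10 ng, and were used as 2 libraries of that group with no experiment number. No column was assigned to the uninjected progesterone sample, so the effect of progesterone without the morpholino, and its interaction with the morpholino, were not analysed here. The design fixed before the data were examined counted on 7 libraries in 4 groups, and 6 libraries in 3 groups were fitted. Nothing in the labels says that libraries of a group came from separate clutches, and the uninjected pair is named by 5 and 10 ng, so the p-values measure only the spread between these libraries, which may be technical.

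The number of sequenced fragments is unknown. Low FPKM values fall on steps of single fragments, and the steps of genes under 0.6 FPKM, compared between libraries with a tolerance of 0.01 on the log2 scale, gave depths relative to the 5 ng uninjected library. Their 95% intervals come from 100 bootstrap draws over genes and cover that comparison only. The share of summed FPKM in small non-coding RNA was taken over 3977 genes with names of that class.

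The main test was limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend) on log2(FPKM + 1), for the 13155 genes with a mean FPKM of at least 1, with 3 groups as means, 3 residual degrees of freedom and Benjamini-Hochberg adjusted p of at most 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes, and are given with their standard error. No exact permutation test of 2 libraries against 2 can give a two-sided p below 0.333. The median of all tested genes moved by -0.07 with the morpholino, by -0.58 with progesterone and by -0.67 with both, so a relative change is the log2 fold change minus that median. Scaling by median-ratio size factors brought these medians to 0.01, -0.08 and -0.09. Subtracting the median does not fully remove a shared factor, which moves low genes less than high ones on this scale. The progesterone median was -0.788 with a pseudocount of 0.1 and -0.295 with 5.

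Of 21 gene lists fixed before the data were examined, 19 had at least 3 tested genes. The blood and endothelium lists had 2 tested genes each and were not tested. The muscle, neural, blood, endothelium, epidermis, notochord, endoderm and otic lists were fixed as markers of other cell types. Their changes can reflect which cells were sorted as well as changes within cells, and these were not separated. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the 19 lists of a comparison. Camera compares the list with the other genes. Fry tests against no change, on values whose median moved with progesterone, so its p-values are not given for the comparisons with progesterone. Single-gene tests, over the list alone or over all genes, also test against no change. With progesterone, their counts on the deposited scale therefore carry the same shift toward lower. In the morpholino comparison no list passed with directional fry (smallest adjusted p = 0.223). The correlation across genes of the morpholino and the progesterone effects was set beside 100 simulated data sets with no effect, because both effects contain the morpholino DMSO libraries.

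The rule for naming genes was fixed in advance. It took ctr9, the other PAF1 complex genes, sox10, crestin, foxd3 and ddx21, then in each comparison the 8 genes with the largest rise and the 8 with the largest fall among called genes with a mean FPKM of at least 5 and no overlap between the groups, then up to 4 members with the largest change from each described list. Places left empty were filled by the smallest unadjusted p, and such genes are named as not passing. The rule left placeholder names out, and the 2 that are named, si:ch211-8i17.2 and zgc:173552, complete a count and were chosen after their values were seen. Other list members that are named were chosen after their values were seen. Crestin has no row under that name in the table.

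The script was tested on simulated data with known changes, in 10 sets of 13155 genes. For the morpholino comparison it called 0% of genes changed by a log2 fold of 1, 0.448% at 2 and 5.61% at 3, and for progesterone in morphants 0%, 0.149% and 4.85%. The estimated folds were close to the simulated ones (medians of 1.02, 1.99 and 3.00 for the morpholino comparison), so a gene missing from the calls is not shown to be unchanged.

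Alternatives were pseudocounts of 0.1 and 5, no filter, a mean FPKM of at least 5, median-ratio and quantile scaling, only the libraries compared, a robust prior, the experiment number as a block, and leaving out each library. Removal of small RNA genes, and median-ratio scaling without the progesterone library of experiment 2, were added after the data were seen.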

Results

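Sox10 marks neural crest, otic and later glial cells in the zebrafish embryo, and the series concerns nucleotide stress, the RNA helicase DDX21 and transcription elongation. The deposited FPKM cover 6 libraries of sorted sox10-positive cells: 2 of uninjected embryos in DMSO, 2 labelled ctr9 morpholino in DMSO and 2 labelled ctr9 morpholino in 32 µM progesterone.

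The progesterone libraries held fewer genes than the others. At 1 FPKM or more, 13181 and 13534 genes were found in the uninjected libraries, 13447 and 13065 in the morpholino DMSO libraries, and 11788 and 9581 in the progesterone libraries. Of genes at 1 to 5 FPKM in uninjected cells, 15.7% and 28.9% were listed at 0 in the progesterone libraries, against 4.65% and 6.15% in the morpholino DMSO libraries. The 50 highest genes took between 30.7% and 46.9% of summed FPKM. Small non-coding RNA genes took 21.7% and 30.9% of summed FPKM with progesterone and at most 16.6% elsewhere. The summed FPKM was 218077 in the progesterone library of experiment 2 and between 356240 and 366907 in the other 5. Relative depths read from the FPKM steps lay between 1 and 1.47, with 1.24 (95% interval 1.24 to 2.47) and 1.05 (1.05 to 2.10) in the progesterone libraries. Synthetic ERCC spike-in transcripts were also in the table, with amounts that the labels do not give. They summed to 1.96 and 22.4 FPKM in the uninjected libraries, 229.1 and 139.4 in the morpholino DMSO libraries and 172.9 and 69.3 in the progesterone libraries, with at most 23 of 92 above 0, and were not used for scaling. Across genes, log2 values correlated at 0.915 between the uninjected libraries, at 0.882 between the morpholino DMSO libraries and at 0.775 between the progesterone libraries.

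**Figure D1:**
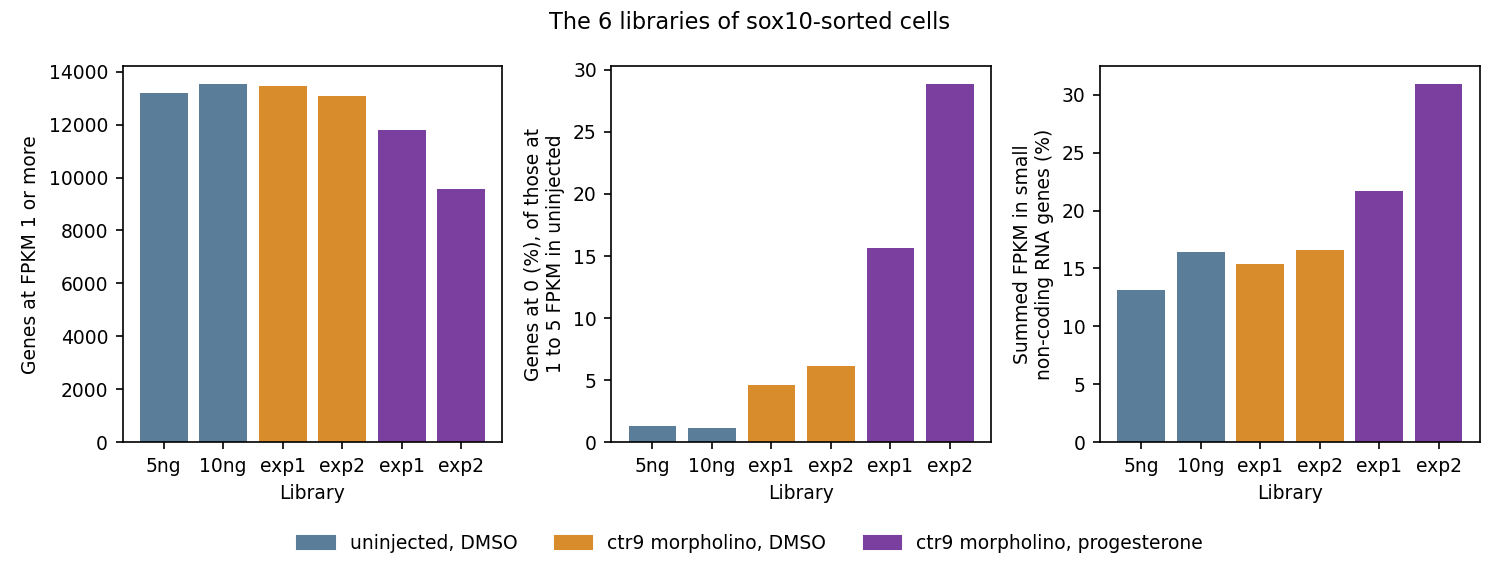
Bars give 1 library each, coloured by group: genes at 1 FPKM or more, the percent listed at 0 among genes at 1 to 5 FPKM in uninjected cells, and the percent of summed FPKM in small non-coding RNA genes. The progesterone library of experiment 2 had 9581 genes at 1 FPKM or more, 28.9% of the low genes at 0 and 30.9% of FPKM in small RNA.

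The targeted gene was ctr9 (ENSDARG00000009170). Its mRNA stood at 16.8 and 19.95 FPKM in the uninjected libraries, at 42.2 and 36.7 FPKM in the libraries labelled ctr9 morpholino in DMSO and at 26.2 and 20.6 FPKM in those with progesterone. The morpholino DMSO libraries were thus higher by 1.06 ± 0.30 on the log2 scale (SE, n = 2 against 2, limma adjusted p = 1). A morpholino need not lower its target's mRNA, so this level does not check the label. The other PAF1 complex genes paf1, leo1, cdc73, rtf1 and wdr61 had log2 fold changes between -0.37 and 0.16 in the same comparison. Sox10 itself stood at 134.1 and 146.7 FPKM in uninjected cells, 160.2 and 125.5 with the morpholino in DMSO, and 191.1 and 60.0 with progesterone. Ddx21 stood at 82.6 and 103.8, at 75.5 and 94.4, and at 98.7 and 60.9 FPKM in the same order. Foxd3 was at most 0.000931 FPKM in 5 of 6 libraries and at 0.659 in the 5 ng uninjected library, and was not tested.

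The first comparison, of libraries labelled ctr9 morpholino with uninjected ones in DMSO, addresses what injection of a ctr9 morpholino does to sox10-positive cells. Genes of the p53 response rose relative to other genes in the libraries labelled ctr9 morpholino, with 17 of 21 members above the median of all genes. Their median relative change was 1.33 (camera adjusted p = 3.19e-10, and adjusted p = 0.336 with an estimated correlation). Tested against no change, the list did not pass (fry adjusted p = 0.223). Mdm2, the ubiquitin ligase that restrains p53, stood at 73.2 and 180.5 FPKM against 19.99 and 22.5 in uninjected cells, a log2 fold change of 2.38 ± 0.49. The cell cycle inhibitor cdkn1a stood at 36.4 and 46.0 FPKM against 9.71 and 15.9 (1.64 ± 0.35). Sesn3 (2.71 ± 0.63), foxo3b (2.57 ± 0.51) and the BH3-only death gene bbc3 (2.04 ± 0.64) were the other members with the largest changes. Adjusted over the list alone, 9 members were higher and 1, gadd45ab, was lower (6 and 0 with median-ratio scaling), while 0 passed over all genes tested. The median relative change was 0.70 without the morpholino DMSO library of experiment 2 and 1.83 without that of experiment 1.

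**Figure D2:**
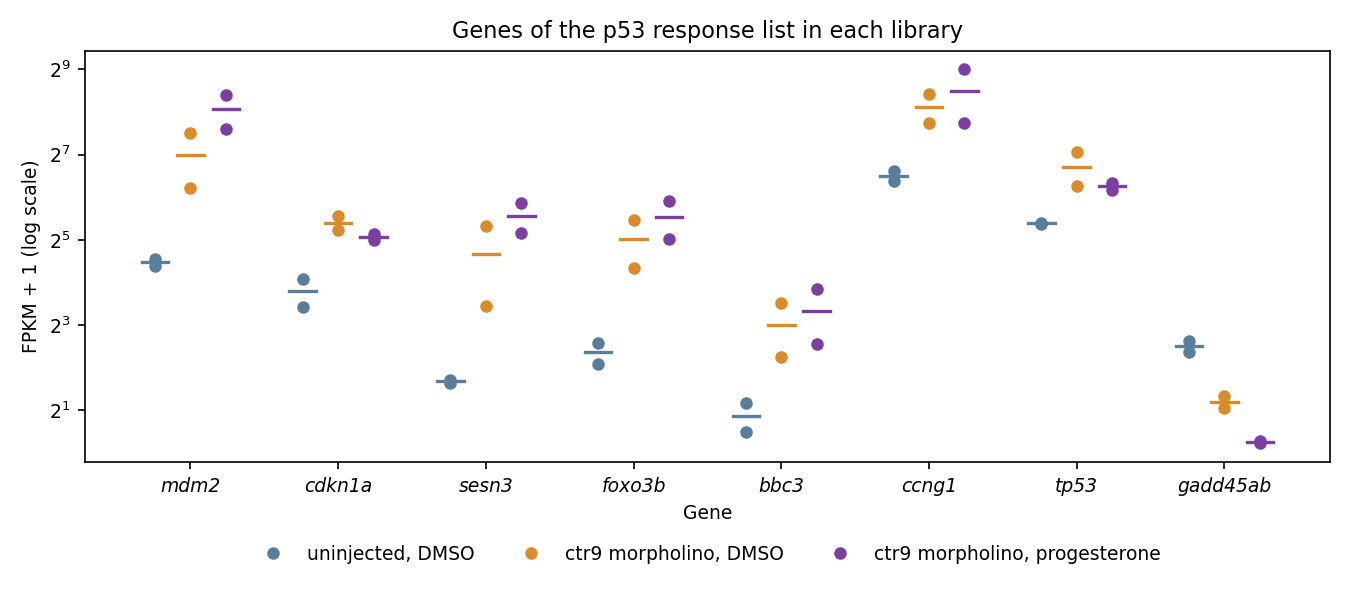
Points give FPKM + 1 on a log axis for 8 genes of the p53 response list in each library, and short lines the mean of the 2 libraries of a group. Mdm2 lay at 19.99 and 22.5 FPKM in uninjected cells and between 73.2 and 339.0 FPKM in the 4 libraries labelled ctr9 morpholino, and gadd45ab was lower in those 4 than in uninjected cells.

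Other lists moved less. Of those below, the otic, neural, epidermal and notochord lists were fixed as markers of other cell types. A change in the mix of sorted cells was not separated from a change within them, here or with progesterone. Ribosomal protein genes fell relative to other genes by a median of -0.32, with 5 of 84 members above the median (camera adjusted p = 3.20e-10, 0.392 with an estimated correlation), although 0 members passed adjusted over the list alone. Otic vesicle genes fell by -0.67 over 8 genes (adjusted p = 0.00307, 0.392 estimated). Within them oc90, an otolith matrix gene, stood at 7.12 and 5.02 FPKM against 24.4 and 21.6 and alone passed adjusted over the list alone (log2 fold change -1.78 ± 0.34), and eya1, six1b and dlx3b had log2 fold changes of -1.08, -0.79 and -0.78. Neural genes were higher by 0.51 over 18 genes (adjusted p = 0.00112, 0.336 estimated), epidermal genes by 0.69 over 12 (adjusted p = 0.0122, 0.392 estimated) and notochord genes by 0.99 over 6 (adjusted p = 0.0386, 0.392 estimated). Among these, the neurogenic gene neurod4 stood at 7.45 and 6.05 FPKM against 2.13 and 1.37, epcam at 2.60 and 12.9 against 0.847 and 0.509, and ctgfa at 11.6 and 11.8 against 2.25 and 2.72. Adjusted over the list alone, 0 neural and 0 epidermal members passed. The notochord members went both ways, with ctgfa higher and KRT18 (2 of 3) lower adjusted over the list alone, the latter at 4.42 and 4.21 against 13.9 and 11.6 FPKM (log2 fold change -1.37 ± 0.34). The epidermal and notochord calls were lost with median-ratio scaling (adjusted p = 0.0923 and 0.137). Against its library's median, the mean log2 level of the epidermal list was 0.80 in experiment 2, -0.02 in experiment 1, and -0.16 and -0.28 in the uninjected libraries.

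Neural crest genes had a median relative change of -0.17 over 23 genes (adjusted p = 0.103). Pax7b, a transcription factor of crest and pigment precursors, stood at 6.95 and 2.16 FPKM against 20.5 and 37.7 (log2 fold change -2.53 ± 0.54), pax7a at 3.27 and 0.583 against 9.02 and 12.5, and twist1a at 72.0 and 34.7 against 103 and 119, and none passed adjusted over the list alone. The remaining lists also missed the threshold, with median relative changes of -0.48 for the pigment lineage (4 genes), 0.03 for nucleotide synthesis (27), -0.09 for nucleolus and ribosome biogenesis (60), 0.02 for transcription elongation and P-TEFb (22), -0.06 for the steroid receptor response (15), -0.10 for the PAF1 complex (6), -0.11 for the cell cycle (29), -0.16 for stress and immediate early genes (36), -0.16 for muscle and somite (5), 0.36 for endoderm, yolk and hatching gland (9), -0.12 for mitochondrially encoded genes (13) and -0.56 for xenobiotic and steroid metabolism (3). The 4 pigment genes tested were tyr and pmela, at most 6.41 FPKM in any library, and paics and gart, also members of the nucleotide synthesis list. Uck2a, a uridine-cytidine kinase gene, stood at 4.09 and 4.37 FPKM against 9.41 and 9.51, and cad, which starts pyrimidine synthesis, at 119.3 and 118.8 against 166.7 and 186.3.

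Gene by gene, limma called 0 genes higher and 2 lower at adjusted p of at most 0.05, and 191 and 351 at an unadjusted p under 0.05. Both called genes are copies of the U6 small nuclear RNA (ENSDARG00000091338, adjusted p = 0.00548, and ENSDARG00000090134, adjusted p = 0.00785), listed at 0 in all 4 libraries labelled ctr9 morpholino and at 128.8 and 156.9, and at 85.9 and 134.5 FPKM, in the uninjected libraries. They are near-identical multi-copy genes whose reads the authors' counting could split, so both are uncertain. Not passing were phlda2, ctgfa, foxo3b, mdm2 and 4 copies of Metazoa_SRP, higher, and SNORA63, a U1 copy, oc90, arhgap31, tnc and pax7b, lower. Leaving out any 1 of the 6 libraries gave between 0 and 3 calls.

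The second comparison, of progesterone with DMSO in embryos labelled ctr9 morpholino, addresses what progesterone does in embryos injected with that morpholino. Cell cycle genes were lower than other genes with progesterone, with 25 of 29 members below the median of all genes and a median relative change of -0.91 (camera adjusted p = 4.28e-05, and adjusted p = 0.757 with an estimated correlation). Plk1, a mitotic kinase, stood at 89.2 and 40.4 FPKM against 299.8 and 228.0 in DMSO (log2 fold change -2.10 ± 0.42), and cyclin gene ccna2 at 17.4 and 18.2 against 77.8 and 78.4 (-2.08 ± 0.30). Adjusted over the list alone, 8 members were lower and 0 higher, and 5 and 0 with median-ratio scaling. Without the progesterone library of experiment 2 the median relative change was -0.51 (adjusted p = 2.2e-05). Ube2c (-2.54 ± 1.13), ccnb2 (-2.32 ± 0.87) and ccne2 (-2.11 ± 0.66) had the largest changes with nusap1 (-2.26 ± 0.64), and of these 4 nusap1 passed. In the progesterone library of experiment 2, ube2c and ccnb2 were listed at 0.

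**Figure D3:**
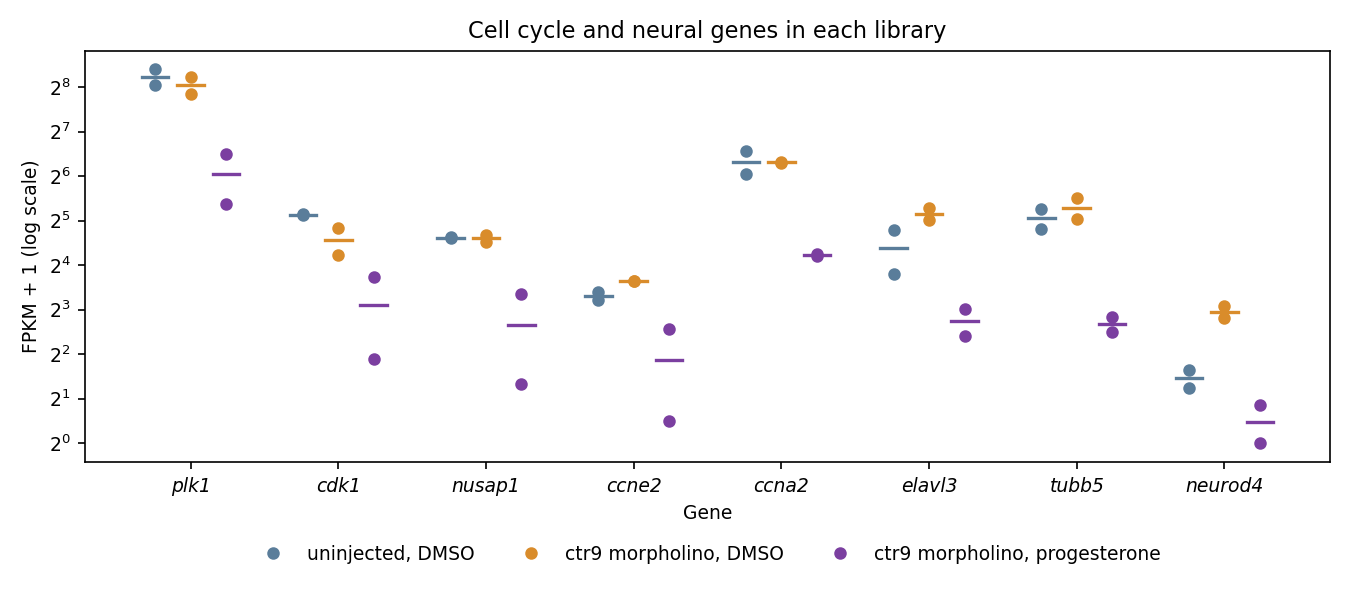
Points give FPKM + 1 on a log axis for 5 cell cycle genes and 3 neural genes in each library, and short lines the mean of the 2 libraries of a group. Plk1 lay at 89.2 and 40.4 FPKM with progesterone and between 228.0 and 335.4 FPKM in the other 4 libraries.

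Neural genes, higher in the first comparison, were lower with progesterone by a median relative change of -1.005 (camera adjusted p = 4.11e-06, 0.228 with an estimated correlation). Adjusted over the list alone, 14 of 18 members were lower, and 8 with median-ratio scaling. Both comparisons contain the morpholino DMSO libraries with opposite sign, so a turn between them can in part arise with no effect. The neuronal tubulin gene tubb5 stood at 6.15 and 4.61 FPKM against 44.4 and 31.9, elavl3 at 7.11 and 4.27 against 38.0 and 31.3, stmn1b at 0.0414 and 1.17 against 10.1 and 8.33, and neurod4 at 0.806 and 0 against 7.45 and 6.05. Endoderm, yolk and hatching gland genes were lower by -1.04 over 9 genes (adjusted p = 0.018, 0.757 estimated), among them the lipoprotein genes apoeb, at 8.36 and 2.98 against 80.2 and 66.7 FPKM, and apoc1l, listed at 0 against 3.42 and 4.31. Mitochondrially encoded genes were lower by -1.12, with 0 of 13 above the median (adjusted p = 0.0204, 0.757 estimated), and that call rested on the progesterone library of experiment 2: without it and with median-ratio scaling the median relative change was -0.08 (adjusted p = 0.555). Mt-atp8 stood at 283.1 and 6.29 FPKM in the 2 progesterone libraries and at 406.1 and 550.7 in DMSO.

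Genes of the p53 list were again above other genes, by 0.92, with 19 of 21 above the median (camera adjusted p = 4.11e-06, 0.667 estimated). Mdm2 stood at 193.5 and 339.0 FPKM against 73.2 and 180.5 (relative change 1.73). Adjusted over the list alone only sesn2 passed, at 20.3 and 13.0 against 2.18 and 1.70 FPKM, a stress gene that is also a target of the amino acid response, and pmaip1 was listed at 78.3 FPKM in 1 progesterone library and at 0 in the other 5 libraries. The call of the list was lost without the morpholino DMSO library of experiment 1 (median relative change 0.48, adjusted p = 0.0621) and with median-ratio scaling without the progesterone library of experiment 2 (0.44, adjusted p = 0.0969).

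Nucleotide synthesis genes did not pass as a list (median relative change -0.30 over 27 genes, adjusted p = 0.311), and its members went both ways. Rrm2, a subunit of ribonucleotide reductase, stood at 27.9 and 12.05 FPKM against 98.8 and 74.9 (log2 fold change -2.16 ± 0.43), and umps, of pyrimidine synthesis, and adsl, of purine synthesis, also passed adjusted over the list alone (-1.42 ± 0.34 and -1.51 ± 0.33). Shmt2 and mthfd2, of mitochondrial one-carbon metabolism, stood at 48.4 and 29.6 against 18.6 and 16.7, and at 20.6 and 14.3 against 6.72 and 7.10 FPKM, and did not pass as deposited. With median-ratio scaling shmt2 and mthfd2 were higher adjusted over the list alone (adjusted p = 0.00523 and 0.00525) and, of the lower genes, rrm2 alone passed (adjusted p = 0.00824). Of the steroid receptor list, with a median relative change of 0.11 over 15 genes (camera adjusted p = 0.588), sgk1 stood at 1.603 and 5.91 FPKM against 15.3 and 24.9 and tsc22d3 at 0 and 0.049 against 2.91 and 1.96. Of the 15 genes, 8 lay above the median of all genes. Tsc22d3 is a low gene, and more low genes were listed at 0 with progesterone. Over the list alone 0 members were higher and 2 lower, and 2 and 1 with median-ratio scaling. Neural crest genes had a median relative change of 0.25 over 23 genes (adjusted p = 0.208), which passed with median-ratio scaling (0.39, adjusted p = 0.0059). Nucleolar genes moved by 0.03, ribosomal protein genes by 0.37 and elongation genes by -0.31, not passing, and ribosomal protein genes passed with median-ratio scaling (0.53, adjusted p = 6.39e-09). Stress and immediate early genes had a median relative change of 0.39 (adjusted p = 0.232, and 0.00304 with median-ratio scaling). Also not passing were the otic (0.14), epidermal (-0.28), PAF1 complex (-0.20), pigment (0.52), muscle (0.07), notochord (-0.25) and xenobiotic (0.23) lists. Of the otic genes oc90 was higher over the list alone (1.16 ± 0.34), and stm and dlx3b were lower (-2.42 ± 0.37 and -2.37 ± 0.50).

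Gene by gene, limma called 0 genes higher and 0 lower, with a smallest adjusted p of 0.14. At an unadjusted p under 0.05, 247 genes were higher and 2609 lower, and 980 and 1248 after median-ratio scaling, which called 1 gene: igfbp1a (ENSDARG00000014947), a binding protein of insulin-like growth factors, at 98.8 and 41.2 FPKM against 2.37 and 1.85 (log2 fold change 4.39 ± 0.48 as deposited, 4.98 scaled with adjusted p = 0.0457). Not passing in the deposited scale, the genes with the smallest p were sesn2, cbsb, histh1l, pyroxd2, a U5 copy and 2 copies of Metazoa_SRP, higher, and meis2a, cox6c, apoeb, tuba1c, pomp, SNORA79, a U1 copy and SNORA27, lower. The count hung on single libraries: without the progesterone library of experiment 1, 262 genes were higher and 4004 lower, and without that of experiment 2, 19 and 5.

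**Figure D4:**
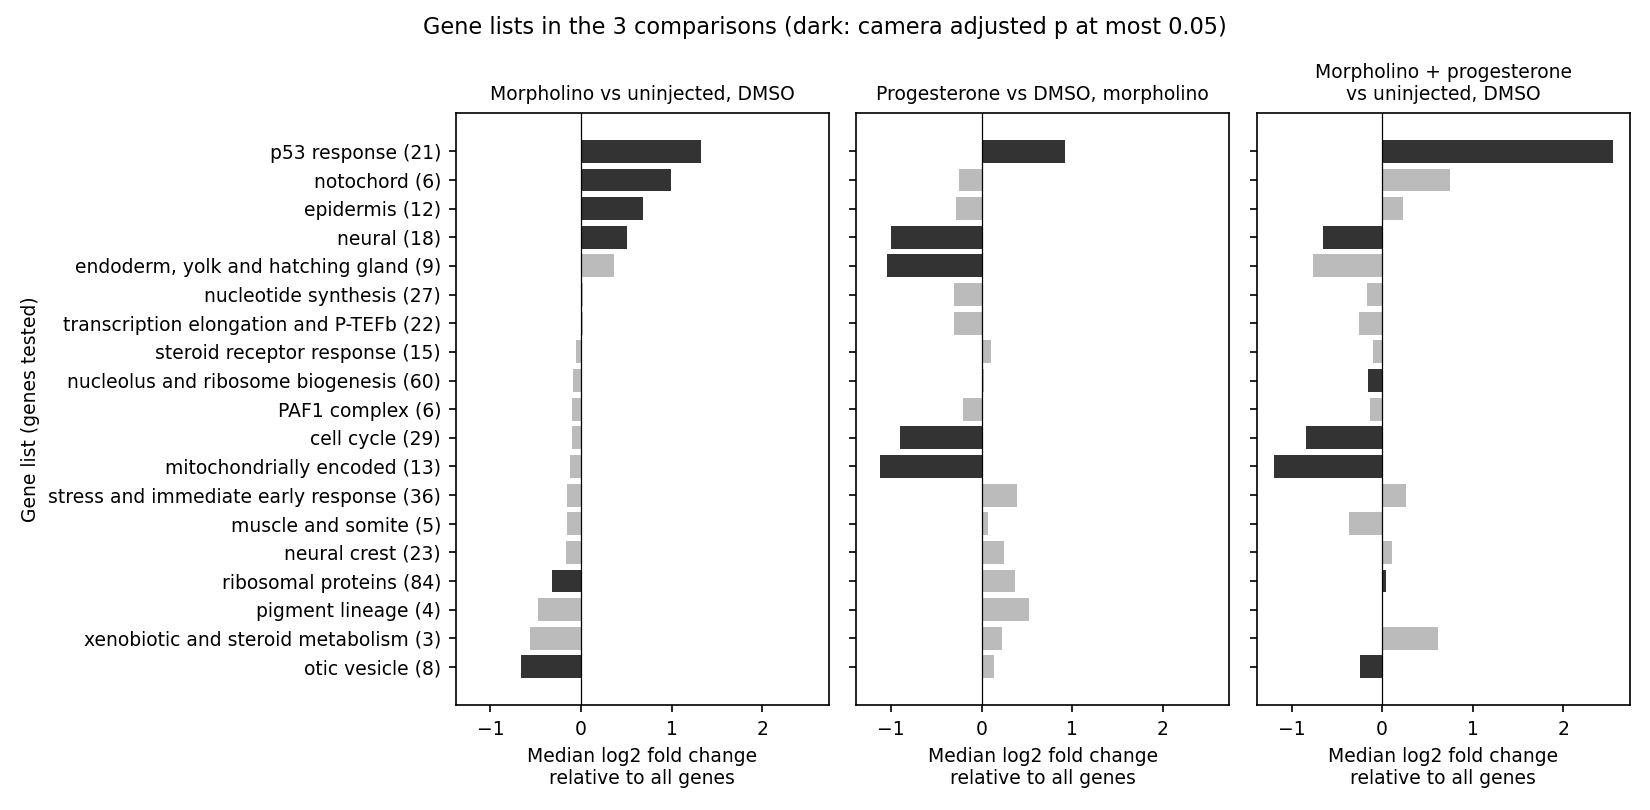
Bars give the median log2 fold change relative to all tested genes for 19 gene lists (number of genes tested in brackets) in the 3 comparisons, dark where camera with a preset correlation passed at adjusted p of at most 0.05. The p53 list had medians of 1.33, 0.92 and 2.54, and the neural list 0.51, -1.005 and -0.66.

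The third comparison, of libraries labelled ctr9 morpholino in progesterone with uninjected ones in DMSO, gives the joint difference from the control. The p53 list was the furthest above other genes, by a median relative change of 2.54 with 20 of 21 members above the median (camera adjusted p = 1.87e-21, 0.244 estimated). Adjusted over the list alone 11 members were higher, with mdm2 at 3.53 ± 0.49 and sesn3 at 3.84 ± 0.63 on the log2 scale, and gadd45ab was lower. Cell cycle genes were lower by -0.84 (adjusted p = 2.60e-06, 0.742 estimated), with 18 of 29 lower over the list alone, including plk1 (-2.28 ± 0.42) and cdk1 (-2.31 ± 0.62), but 4 of 29 with median-ratio scaling. The cell cycle median was -0.52 with that scaling and no progesterone library of experiment 2 (adjusted p = 1.59e-06). Neural genes were lower by -0.66 (adjusted p = 0.0067, 0.364 estimated), with 9 of 18 lower over the list alone but 1 with median-ratio scaling, and the call was lost without the progesterone library of experiment 1 (-0.57, adjusted p = 0.182). Mitochondrially encoded genes were lower by -1.20 (adjusted p = 0.0166, 0.981 estimated), and by -0.20 without the progesterone library of experiment 2 and with median-ratio scaling (adjusted p = 0.407).

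Otic genes were lower by -0.24 (adjusted p = 0.0308, 0.742 estimated), with stm, a starmaker gene of otoliths, at 0.881 and 0.380 FPKM against 14.7 and 11.4, and dlx3b listed at 0 against 7.12 and 8.75. The otic and nucleolar (-0.16, adjusted p = 0.0166, 0.981 estimated) calls were lost with median-ratio scaling (adjusted p = 0.167 and 0.851). For ribosomal proteins camera gave a fall (adjusted p = 0.0451, 0.981 estimated) with a mean log2 fold change of -0.63 but a median relative change of 0.04, and a rise with median-ratio scaling (0.25, adjusted p = 0.0447), so no direction is given. Pax7b, of the neural crest list (median relative change 0.11, adjusted p = 0.97), stood at 2.40 and 2.63 FPKM against 20.5 and 37.7 and passed over the list alone. The other lists did not pass, with median relative changes of -0.26 for elongation, -0.76 for endoderm, yolk and hatching gland, 0.75 for notochord, -0.16 for nucleotide synthesis, 0.23 for epidermis, -0.10 for the steroid receptor response, 0.26 for stress, -0.14 for the PAF1 complex, 0.62 for xenobiotic metabolism, -0.37 for muscle and 0.01 for pigment. With median-ratio scaling the endoderm, yolk and hatching gland list passed as lower (camera adjusted p = 0.0201) and the stress list as higher (camera adjusted p = 0.0408). Limma called 0 genes higher and 2 lower, the same U6 copies, with 233 and 3030 at an unadjusted p under 0.05. Median-ratio scaling called 9 higher, of which 6 were copies of Metazoa_SRP, multi-copy and as uncertain as U6, and the others igfbp1a, cbsb, a cystathionine beta-synthase gene, and si:ch211-8i17.2, and 3 lower, the U6 copies and zgc:173552, and leaving out 1 library gave between 0 and 4552 calls, the highest without the progesterone library of experiment 1.

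Whether progesterone moved genes against the morpholino effect was examined across the 13155 genes, which are not independent replicates. The 2 effects correlated at r = -0.345 with a covariance of -0.181. They share the morpholino DMSO libraries with opposite sign, and simulated data with no effect gave r = -0.5 and a covariance of -0.237 with a spread pooled over groups, and r = -0.408 and -0.169 with each group's own spread. Observed minus simulated covariance was 0.056 for the first and -0.0118 for the second. With a different morpholino DMSO library in each effect, r was -0.0657 and 0.01. A reversal of the morpholino effect beyond what the shared libraries give was not detected.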

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

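The settings without small RNA genes, and with median-ratio scaling and no progesterone library of experiment 2, were added after the data were seen. The robust prior, a pseudocount of 5 and the replicate block left the count of called genes in each comparison unchanged. For the morpholino comparison (2 called genes), the count was 0 with a pseudocount of 0.1, 1 without a filter, 1 at a mean FPKM of at least 5 and 0 without small RNA genes, and between 0 and 3 when 1 library was left out (1 without morpholino DMSO experiment 1). For progesterone (0 called), it was 1 with median-ratio scaling, 1 with quantile scaling, 1 without small RNA genes and 21 with median-ratio scaling and no progesterone library of experiment 2, and between 0 and 4266 when 1 library was left out (1 without morpholino DMSO experiment 1, 24 and 4266 without progesterone experiment 2 and 1). A group of 1 library takes its spread from the other groups in the fit. For both together (2 called), it was 0 with a pseudocount of 0.1, 1 without a filter, 28 at a mean FPKM of at least 5, 12 with median-ratio scaling, 11 with quantile scaling, 0 with only the libraries compared, 0 without small RNA genes, 67 with median-ratio scaling and no progesterone library of experiment 2, and between 0 and 4552 when 1 library was left out (62 and 4552 without progesterone experiment 2 and 1). Removing small RNA genes took the U6 copies out by construction, and elsewhere the cause was not tested.

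Of the lists, 5 passed with progesterone, 8 with median-ratio scaling and 8 without small RNA genes. For both together 7 passed, with 2 at a mean FPKM of at least 5, 4 with quantile scaling, 4 with only the libraries compared, 3 with median-ratio scaling and no progesterone library of experiment 2, and as few as 3 when 1 library (the 5 ng uninjected one) was left out. For the lists fixed in advance, the estimated correlation was run on the deposited scale alone, and no call held with it there. The p53 list in the morpholino comparison kept its direction and its call under every alternative run with the preset correlation. In the third comparison the test of ribosomal proteins turned upward, with median relative changes of 0.247 under median-ratio scaling, 0.201 without small RNA genes and 0.124 with median-ratio scaling and no progesterone library of experiment 2, and the cause was not tested.

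The correlation of the effects ranged from -0.502 to -0.249 when 1 library was left out (-0.502 without morpholino DMSO experiment 1, -0.486 without experiment 2) and was -0.0657 and 0.01 with disjoint libraries, by construction free of the shared term. Differences between experiments in DMSO and in progesterone morphants, a check of pairing, correlated at 0.0762 across genes. Across lists they had the same sign in 12 of 19 (r = 0.352), with experiment 2 above experiment 1 by 0.809 and 0.59 for p53, 0.821 and 0.74 for epidermis and 0.517 and 0.559 for notochord, so a shared experiment is left open for these lists. With the experiment as a block 2, 0 and 2 genes were called and the correlation of effects stayed at -0.345. The block changed list calls, from 6 to 8 with the morpholino (neural crest and nucleolus lower, both at adjusted p = 0.0444), from 5 to 6 with progesterone (elongation lower, 0.0407) and from 7 to 6 for both together (otic no longer called, 0.0568). The additive model equals the fit of 3 groups when the uninjected progesterone group is absent and was not run. The absolute depth is unknown, so no floor can be set for genes listed at 0.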

Other observations

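The list of amino acid and ATF4 response genes, the list of sterol genes, the histone genes and all tests of explanations except that of quantile scaling were chosen after the results they bear on were seen. The quantile test was written before its own value was seen, but after the list's median relative change with median-ratio scaling (1.51) had been seen.

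With progesterone, genes of the amino acid and ATF4 list were above other genes in embryos labelled ctr9 morpholino, with a median log2 fold change of 0.835. The list did not pass with an estimated correlation (camera adjusted p = 0.203). Some members, such as psph, gars and cth, were lower than in DMSO, and others were higher. Phgdh, the first enzyme of serine synthesis, stood at 79.8 and 43.0 FPKM against 11.6 and 17.4 in DMSO (log2 fold change 1.97 ± 0.40), the amino acid transporter genes SLC7A5 at 13.6 and 4.59 against 0.667 and 0.708 and slc3a2b at 19.6 and 9.34 against 2.49 and 1.40, and the alanyl-tRNA synthetase gene aars at 80.8 and 73.9 against 38.8 and 38.5. Of 30 listed genes, 28 lay above the median of all genes and 8 passed adjusted over the list alone, 20 with median-ratio scaling. Igfbp1a, sesn2 and mthfd2, among the 8, had been seen before the list was written. Adjusted over the members not seen before, phgdh, herpud1, slc3a2b, SLC7A5 and aars passed on the deposited scale. In the morpholino comparison the list had a median relative change of -0.17. The morpholino DMSO libraries are shared by both comparisons, and some members were low there. Herpud1 stood at 7.53 and 10.8 FPKM in them, at 21.8 and 29.0 in uninjected cells and at 26.2 and 25.6 with progesterone. For progesterone morphants against uninjected cells in DMSO, the list's median relative change was 1.29 (limma camera adjusted p = 1.01e-16, 0.195 estimated). Histone genes were lower than other genes with progesterone by a median of -1.03 over 19 genes (limma camera adjusted p = 0.00812, 0.49 estimated), by -0.41 without the library of experiment 2 (adjusted p = 0.0773). With the morpholino alone they were already lower, by -0.43 (adjusted p = 0.00199, 0.844 estimated). With progesterone histh1l stood at 98.1 and 128.8 FPKM against 31.8 and 19.9. Some of the 19 rows are copies of multi-copy genes, such as hist2h3c and HIST1H4A. Their reads could be split as for U6, so the rows do not count as 19 separate genes.

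The first pattern is the lower median and the genes at 0 in the progesterone libraries. The FPKM steps put the shallower of these libraries at 1.05 times the shallowest other one. Steps were also matched at multiples of each other, so such a depth is uncertain by a multiple (95% interval 1.05 to 2.10). The steps therefore do not decide whether fewer fragments were sequenced. The larger share of small RNA would alone move the progesterone libraries of experiments 1 and 2 by -0.1 and -0.282 on the log2 scale, against median changes of -0.29 and -0.883. Without small RNA genes and at the same summed FPKM, median changes of -0.229 and -0.158 were left, where the morpholino DMSO libraries differed by 0.124, so most of the fall in experiment 2 went with its small RNA and lower sum, and why the sum was lower was not tested. Fewer captured RNA molecules cannot be told apart from a loss of transcripts in the cells: centred on its median, the difference between replicates was 1.89 times that of the morpholino DMSO group over 4884 genes, but 1 pair of libraries per group does not decide it.

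The second pattern is the p53 list in the libraries labelled ctr9 morpholino. Cells of both groups were dissociated and sorted, so a stress shared by them cannot be seen in this comparison. The stress and immediate early list had a median relative change of -0.159. This speaks only against a handling stress that was stronger in the morpholino libraries and raises that list. A single deviating library is argued against, since the p53 list was above other genes by 0.701 with experiment 1 alone and by 1.83 with experiment 2 alone. Injection of any morpholino, rather than the loss of ctr9, cannot be told apart, because 0 libraries had a control morpholino. Nor can a difference in preparation between the groups. Only the uninjected libraries are named by amount, and their spike-ins summed to 1.96 and 22.4 FPKM, against 69.3 to 229.1 in those labelled ctr9 morpholino. A p53 response to loss of ctr9 is therefore a hypothesis that these libraries leave open.

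The third pattern is the amino acid and ATF4 list with progesterone, with a median relative change of 1.42 (limma camera adjusted p = 4.68e-20, adjusted p = 0.203 with an estimated correlation, 0.0187 estimated with median-ratio scaling). The median was also 1.42 under quantile normalization. A relative change already subtracts the median shift of all genes, so this value says little about scaling as the source. The subtraction is incomplete on log2(FPKM + 1), where a shared factor moves low genes less than high ones. Median-ratio scaling, applied before the log, gave a median of 1.51. The noise of 1 library is argued against, since the median was 1.49 and 1.33 with each progesterone library alone. The 26 members whose values had not been seen when the list was written had a median of 1.31 (limma camera adjusted p = 1.06e-14, 0.203 estimated). Among them, atf3 and ddit3 are also in the stress and immediate early list, which was fixed in advance and tested. The 26 members were measured in the same libraries as those already seen, so they are not an independent test. That progesterone induces this response in embryos labelled ctr9 morpholino is a candidate explanation. Whether it does so without the morpholino was not analysed here, and a link to ctr9 was not tested.

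Genes of sterol synthesis and uptake were above other genes with progesterone. Their median relative change was 0.861 over 13 genes (limma camera adjusted p = 9.5e-05, 0.234 estimated), but 0.353 without the library of experiment 1 (median log2 fold change -0.54, adjusted p = 0.00919) and 0.841 without that of experiment 2 (adjusted p = 0.000676). Srebf2, the sterol-responsive transcription factor gene, stood at 24.7 and 17.4 FPKM against 7.39 and 6.25, and only srebf2 and FDFT1 passed adjusted over the list alone, while hmgcrb stood at 4.44 and 3.12 against 6.46 and 8.93.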
